A study of Mus musculus with 9 samples.

How the data were processed

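RNA from fluorescence-sorted hippocampal pyramidal neurons was profiled in 9 libraries. Per the labels' protocols, hippocampi were cut in 300 um slices and digested with papain, dead cells were excluded with DAPI, and cells fluorescent for the injected mCherry vector were sorted. The submitters' processing notes name bcl2fastq 2.17.1.14, Trimmomatic 0.30, HISAT2 2.0.1, HTSeq 0.6.1 and the genome build mm10. Their roles, order and parameters, the strand setting and the gene annotation release are not given in the sources used here. Per the file headers, the authors deposited a raw count and an FPKM value (a count normalised to gene length and library total) for each of 51912 Ensembl genes in each library. The counts were whole numbers with a different total in each library, and no entry lacked a gene. The deposited FPKM values were used only to check the counts. Over 5162 genes, the ratio of count to FPKM, taken relative to S1001, differed from the ratio of library totals by at most 0.174%. FPKM values were not recalculated from gene lengths. How reads that match several genes were treated is not given in the sources used here, and values of genes with near-identical copies, of pseudogenes and of genes with overlapping neighbours are therefore uncertain, whether or not this is said beside them.

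The labels of each library give the same source and strain and a serial title, and no dose. The deposited tables also carry a letter and a number per library in their names and column headers, which the labels do not explain and which were not used to assign groups. All 9 libraries were left without a group, 0 of 9 having one, and replicate numbers 1 to 9 stand for S1001 to S1009 as names only. No differential expression between doses was tested, no library was assigned to a dose from its values, and no means with standard deviations are given. Gene symbols and coordinates came from GENCODE release M21 on the same build, which held 51633 (99.46%) of the gene identifiers.

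Counts were scaled to CPM with TMM factors from edgeR 4.0.16 in R 4.3.3, and log2(CPM + 1) was used with a pseudocount of 1 CPM. A gene was described when its mean was at least 1 CPM, and its spread was the difference between the second highest and the second lowest library, with 2-fold as the threshold. The common biological coefficient of variation came from edgeR with an intercept alone. Each gene list was scored per library as the mean of its members' log2 values, centred on each gene's median. The range of the score was ranked among 10000 random lists of the same size, matched on mean expression in 20 bins. A list was counted as ranging more widely than chance at a percentile of 95 or more, and lists with fewer than 3 members at 1 CPM were given as levels only. The percentile describes these libraries and is not a p-value. Pairs of libraries were compared by chi-square over genes with at least 10 counts in the pair. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.

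The design, the gene lists and the rule for named genes were fixed before the data were examined. The rule named the 20 genes of largest spread and the 10 of highest mean, and the 5 in which a single library stood farthest from the next. It also named, of each list, the 2 most abundant and the 2 most variable members, and every member of the sex check and virus entry lists. Some of the genes the rule names are not reported here. Genes chosen by spread or by a single library had a mean of at least 10 CPM. The lists covered neuronal subtypes, glia, vascular, blood and lymphoid cells, interferon and antigen presentation genes, stress, cell death, synaptic, channel, metabolic, ribosomal and mitochondrial genes. Lists of plasma cell, border macrophage, neutrophil and dendritic cell genes were added after the data had been seen. Alternatives were total-count scaling, DESeq2 1.42.0 size factors, totals without mitochondrial genes, pseudocounts of 0.5 and 5 CPM, no minimum or a minimum of 10 CPM, and the full range in place of the trimmed spread. Others were 5 expression bins, the median as list score, and leaving out each library. Leaving out S1002 and S1003 together was added after seeing the data.

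Of 12 correlations between measures across libraries planned beforehand, 11 met the planned rule on gaps within a measure. They are not given, because whole profiles fell into separate clusters, so that the libraries are not independent samples for a pooled correlation. This departs from the plan.

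The calculations were tested on simulated data with 14798 genes, in which 200 genes were raised in 3 of the libraries. The spread recovered 74% of genes raised 2-fold and 100% of genes raised 4-fold, and 0% of unchanged genes passed 2-fold. In unchanged libraries 7% of random lists reached percentile 95, and 100% of lists raised 2-fold did. The simulated libraries were independent draws without clusters, with a smaller biological coefficient of variation than the 0.527 of the data. These rates therefore test the calculations and are not error rates for the real libraries. The floor for a count of 0 is 3 counts. Reads were not separated by molecular identifiers here, so floors cover counting error only.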

Results

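The series measured RNA from hippocampal pyramidal neurons of male C57BL/6 mice that carry Cre recombinase under the Camk2a promoter. An adeno-associated virus of serotype 5 (rAAV5) delivered a Cre-dependent mCherry, a red fluorescent protein, so that Cre-positive neurons became fluorescent and could be sorted. Per the labels, 3 doses of 2.88e+08, 2.88e+09 and 2.88e+10 vector genomes were injected and cells were collected 3 weeks later, to ask how the dose of the vector alters the transcriptome. The series describes 9 samples in 3 groups of 3. The labels of the individual libraries, titled S1001 to S1009, give no dose, so every library was left without a group and no comparison between doses was made. Values are given per library, or as the range and median over the 9 libraries, and the spread described includes any effect of dose.

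Total gene counts in S1001 to S1009 were 12136830, 12987475, 13105465, 19151596, 13873127, 13424364, 15371545, 16299235 and 16937257. Genes with at least 1 count numbered 25092, 25397, 25478, 23214, 24910, 25227, 19261, 20255 and 17906 in the same order. Genes with at least 10 counts ranged less, from 14234 to 15910 with a median of 15598. Protein-coding genes held 96.5% to 97.4% of the counts of a library. The same 10 genes, those of highest mean over the 9 libraries, held 4.37% to 6.09%. Mitochondrially encoded genes held 1.45%, 1.45%, 1.52%, 1.15%, 1.09%, 0.866%, 0.482%, 0.610% and 0.756%. A count of 0 allows a level of up to 0.1579 to 0.2459 CPM (counts scaled to a common library total), depending on the library, which covers counting error only.

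**Figure D1:**
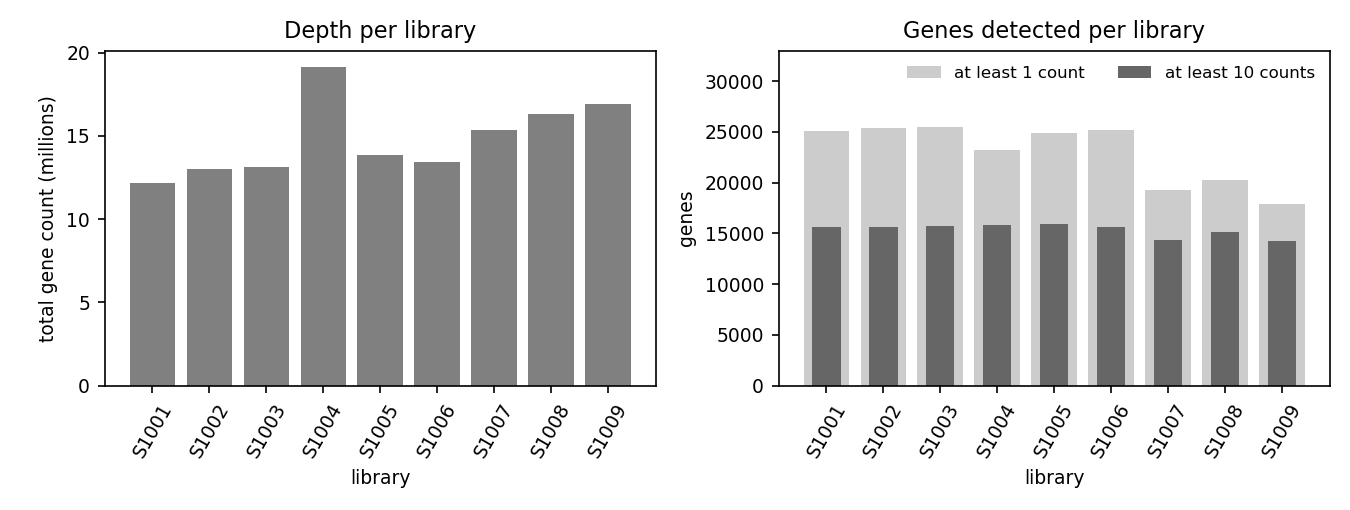
Total gene count (left) and number of genes detected (right) in each of the 9 libraries, with light bars for at least 1 count and dark bars for at least 10 counts. S1004 had the highest total at 19151596 counts, and S1009 had the fewest genes with at least 1 count at 17906.

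Transcripts of excitatory neurons were abundant in every library. Slc17a7, the vesicular glutamate transporter of forebrain excitatory neurons (ENSMUSG00000070570, chromosome 7, 45163949 to 45176142, build mm10), ranged from 184 to 586 CPM. Nrgn, a postsynaptic calmodulin-binding protein, ranged from 576 to 4203 CPM, and Gria2, an AMPA receptor subunit, from 1224 to 1965 CPM. Of the 14 pyramidal neuron genes scored, 2 differed at least 2-fold between the second highest and second lowest library. The range of the list score was 0.88 on the log2 scale, at percentile 88.56 of matched random lists. The CA1, CA2 and CA3 lists ranged over 1.12, 1.05 and 0.81, at percentiles 88.79, 86.35 and 64.89. Single members varied more. Ccn3, a secreted matricellular protein, measured 102, 98.4, 97.2, 980.3, 492, 989.6, 114, 138 and 948 CPM in S1001 to S1009, and Wfs1, an endoplasmic reticulum protein enriched in CA1, ranged from 86.3 to 522 CPM. Pcp4, enriched in CA2, ranged from 50.7 to 199 CPM, and Bok, a CA3 gene of the BCL2 family, from 8.76 to 27.9 CPM. With scores taken from the median of members, these 4 lists reached percentiles 99.89, 99.93, 99.03 and 95.7.

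Genes of dentate granule cells and of inhibitory neurons were also present and uneven. The dentate granule list ranged over 1.91 (percentile 98.62), and 8 of 9 members passed 2-fold. C1ql2, a synaptic organiser of mossy fibres, measured 21.1, 19.5, 22.9, 19.8, 2.69, 13.4, 5.38, 36.1 and 2.28 CPM in S1001 to S1009. The inhibitory neuron list ranged over 2.26 (percentile 99.95), and 11 of 12 members passed 2-fold. Gad1, which makes the transmitter GABA (ENSMUSG00000070880, chromosome 2, 70553072 to 70602014), measured 37.7, 36.4, 43.8, 241, 131, 224, 353, 574 and 141 CPM. Sst, the neuropeptide somatostatin, ranged from 81.0 to 517 CPM. Vip, the neuropeptide of another interneuron class, reached 164 CPM in S1007 and 0.305 CPM in S1008.

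Across the 14787 genes with a mean of at least 1 CPM, 3911 (26.4%) differed at least 2-fold between the second highest and the second lowest library, and 481 at least 16-fold. The median difference was 0.66 on the log2 scale. Between the highest and lowest library, 7016 genes stayed under 2-fold. The biological coefficient of variation over the 9 libraries, doses mixed, was 0.527. The count of 3911 fell to 1955 with a pseudocount of 5 CPM and to 1770, of 9646 genes, with a minimum mean of 10 CPM. Of 31 gene lists scored, 16 ranged more widely than 95% of matched random lists. The nominal rate gives 1.55 lists by chance, but 7% of random lists reached this level in simulated unchanged libraries. Several lists varied over the libraries in the same way, so the 16 are not independent. With the median of members as score, 26 lists ranged more widely than 95% of random lists.

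Of the 20 genes with the largest spread, 6 encode antibody chains or the chain that joins them: Igkc, Ighg2c, Jchain, Ighg2b, Igha and Igkv6-25. Igkc, the constant region of the kappa light chain (ENSMUSG00000076609, chromosome 6, 70726435 to 70726966), measured 2133, 2180.5, 2168, 0.526, 0.276, 0, 0.673, 0.853 and 0.555 CPM in S1001 to S1009. Jchain, which links antibody polymers, measured 1046, 1131, 1093, 0.421, 1.17, 0.582, 0.202, 0.305 and 0.308 CPM. Ighg2c ranged from 0.0727 to 1565 CPM, Ighg2b from 0 to 845 CPM, Igha from 0 to 619 CPM and Igkv6-25 from 0 to 316 CPM. With S1002 and S1003, the libraries closest to S1001, left out together, an alternative chosen after seeing the data, these 6 genes were under 2-fold apart and the other 14 of the 20 at least 2-fold apart. The spread of Igkc was then 0.54 on the log2 scale, against 10.73 over all libraries, since S1001 was then the only library with a high value and the spread leaves out the highest library. Immunoglobulin genes share sequence, so the division of counts among them is uncertain.

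Transcripts of genes for antigen presentation by MHC class II varied over a wide range. Cd74, the invariant chain (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652), measured 5553, 4953, 5276, 22.2, 241, 19.0, 4.04, 7.74 and 4.62 CPM. H2-Ab1, H2-Aa and H2-Eb1, which encode class II chains, ranged from 0.336 to 1595 CPM, 0.308 to 1357 CPM and 0.986 to 742 CPM. All 6 members scored passed 2-fold, and the score ranged over 7.28 (percentile 100). The summed level of the list was 9511, 8495, 9036, 79.0, 454, 64.7, 48.0, 59.2 and 61.2 CPM. All 10 MHC class I genes passed 2-fold as well, with a range of 5.01 (percentile 100). B2m, the light chain of class I molecules (ENSMUSG00000060802, chromosome 2, 122147686 to 122153083), measured 3934, 3723, 3977, 694, 596, 566, 94.8, 95.1 and 120.2 CPM, and H2-D1 ranged from 33.0 to 2717 CPM. H2-K1 ranged from 1.91 to 1074 CPM and Psmb8, an immunoproteasome subunit, from 0.471 to 187 CPM. H2-K1 and H2-D1 are similar class I genes, so the division of counts between them is uncertain. The summed level of microglial genes in the same libraries was 18555, 17117, 17769, 6099, 4780.1, 4856, 79.7, 145 and 27.5 CPM. Which cells expressed the class I and class II genes is not shown by these values.

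Of the interferon-stimulated genes, 22 of 22 passed 2-fold, and the list score ranged over 4.38 (percentile 100). Members did not all share the same order over the libraries. Ifi27l2a, named after its values were seen, was highest in S1004, at 62.1 CPM against 33.1, 26.2 and 29.6 CPM in S1001 to S1003. Ifit1, an antiviral RNA-binding protein (ENSMUSG00000034459, chromosome 19, 34640871 to 34650009), measured 94.7, 116, 113, 6.53, 2.62, 7.78, 0.0673, 0.183 and 0.246 CPM. Oasl2, an interferon-induced antiviral protein, ranged from 2.56 to 341 CPM and Bst2, which tethers budding virus, from 9.49 to 211 CPM. All 14 inflammatory signalling genes scored passed 2-fold, with a range of 5.50 (percentile 100). Il1b, an inflammatory cytokine, ranged from 0.670 to 658 CPM, and Il1a ranged from 0.308 to 715 CPM. Ccl3 and Ccl4, chemokines, ranged from 0.370 to 571 CPM and 0.678 to 918 CPM. Ccl7, a monocyte chemoattractant, had another order over the libraries, at 193, 191, 211, 760.1, 669, 848, 0.942, 5.24 and 0.924 CPM. So did Ccl2, a scored member of the inflammatory signalling list that was named after its values were seen. It measured 148, 131, 149, 535, 503, 642, 1.28, 4.08 and 0.678 CPM. Nfkbia, the inhibitor of NF-kappaB, ranged from 35.1 to 617 CPM. Microglial genes varied in the same libraries. In S1001 to S1009 the interferon-stimulated score was 2.09, 2.06, 2.06, 0.24, -0.32, 0.02, -2.29, -2.21 and -2.14, the inflammatory signalling score 2.29, 2.25, 2.30, 0.17, 0.45, -0.08, -2.75, -2.83 and -3.21 and the microglia score 2.40, 2.31, 2.37, 0.12, -0.01, -0.18, -4.88, -4.13 and -5.97, all on the log2 scale. These values do not show which cells expressed the interferon-stimulated and inflammatory genes.

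**Figure D2:**
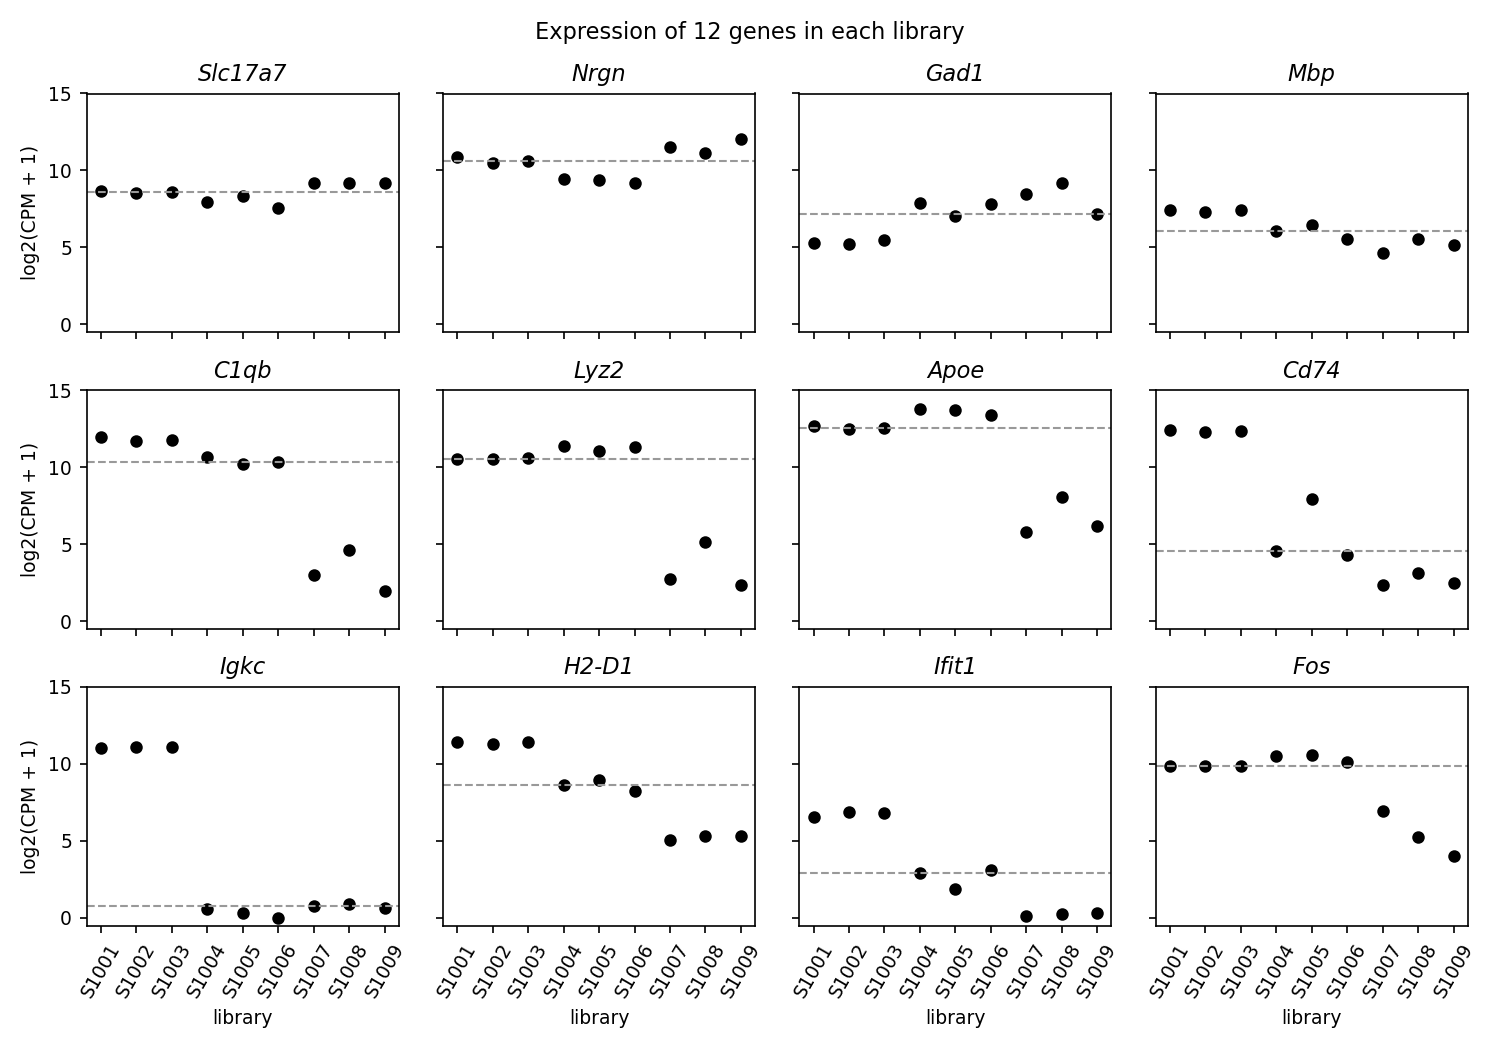
Level of 12 genes in each of the 9 libraries as log2(CPM + 1), with 1 point per library and a dashed line at the median. Igkc ranged from 0 to 2180.5 CPM, while Slc17a7 ranged from 184 to 586 CPM.

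Microglial genes had the widest list range, 8.37 on the log2 scale (percentile 100), and 13 of 13 members passed 2-fold. C1qb, a complement component made by microglia and macrophages (ENSMUSG00000036905, chromosome 4, 136880129 to 136886187), measured 3925, 3326, 3547, 1615, 1166, 1288, 7.00, 23.6 and 2.90 CPM. C1qa and C1qc ranged from 2.77 to 2991 CPM and 3.39 to 3172 CPM. Ctss, a lysosomal protease, measured 3779, 3863, 3816, 414, 417, 423, 9.28, 24.7 and 2.53 CPM. Lyz2, the lysozyme of myeloid cells, measured 1484, 1476, 1564, 2687, 2134, 2523, 5.65, 33.6 and 4.13 CPM. Cst7, a cystatin, ranged from 0 to 698 CPM. T and B lymphocyte genes ranged over 2.92 (percentile 100), with 6 of 6 past 2-fold. Cd79a, a B cell receptor component, ranged from 0 to 13.6 CPM, and Cd4, a coreceptor of helper T cells that macrophages can also express, from 0 to 23.9 CPM.

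Oligodendrocyte genes ranged over 3.80 (percentile 100), and all 11 members passed 2-fold. Mbp, a major myelin protein (ENSMUSG00000041607, chromosome 18, 82475146 to 82585637), measured 171, 159.8, 175, 65.7, 86.3, 46.6, 24.2, 45.0 and 34.3 CPM. Cldn11, a myelin tight-junction protein, ranged from 0.0673 to 34.8 CPM. The oligodendrocyte precursor list ranged over 3.11 (percentile 100), with 8 of 8 past 2-fold, and Olig1, a lineage transcription factor, ranged from 0.308 to 53.2 CPM. Astrocyte genes ranged over 1.49 (percentile 98.47), with 7 of 12 past 2-fold, but reached percentile 86.91 without S1005. Gfap, the astrocyte intermediate filament, ranged from 4.71 to 44.6 CPM, and Slc1a3, a glutamate transporter, from 5.05 to 46.6 CPM. Apoe, a lipid carrier of glia and macrophages (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), was among the 10 most abundant genes and measured 6476, 5698, 5917, 13832, 13535, 10693, 53.7, 266 and 71.2 CPM. Other cell types were represented by few genes, and the endothelial, mural, and ependymal and choroid plexus lists had 2 scorable members each. The endothelial sum of 22.0 to 49.6 CPM was mostly Itm2a, at 19.4 to 43.1 CPM, while Cldn5 and Cdh5, of endothelial junctions, ranged from 0 to 0.138 CPM and 0 to 0.158 CPM. The mural sum of 5.92 to 39.7 CPM was mostly Rgs5, at 4.13 to 27.6 CPM, and Vtn, at 0.122 to 11.0 CPM. The ependymal and choroid plexus sum of 72.8 to 142 CPM was mostly Enpp2, at 61.6 to 126 CPM, and Kl, at 7.86 to 20.2 CPM, while Ttr and Foxj1 ranged from 0 to 0.737 CPM and 0 to 0.246 CPM. Cldn5, Cdh5, Ttr and Foxj1 were named after their values were seen. Erythroid genes summed to 0.183 to 1.103 CPM.

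**Figure D3:**
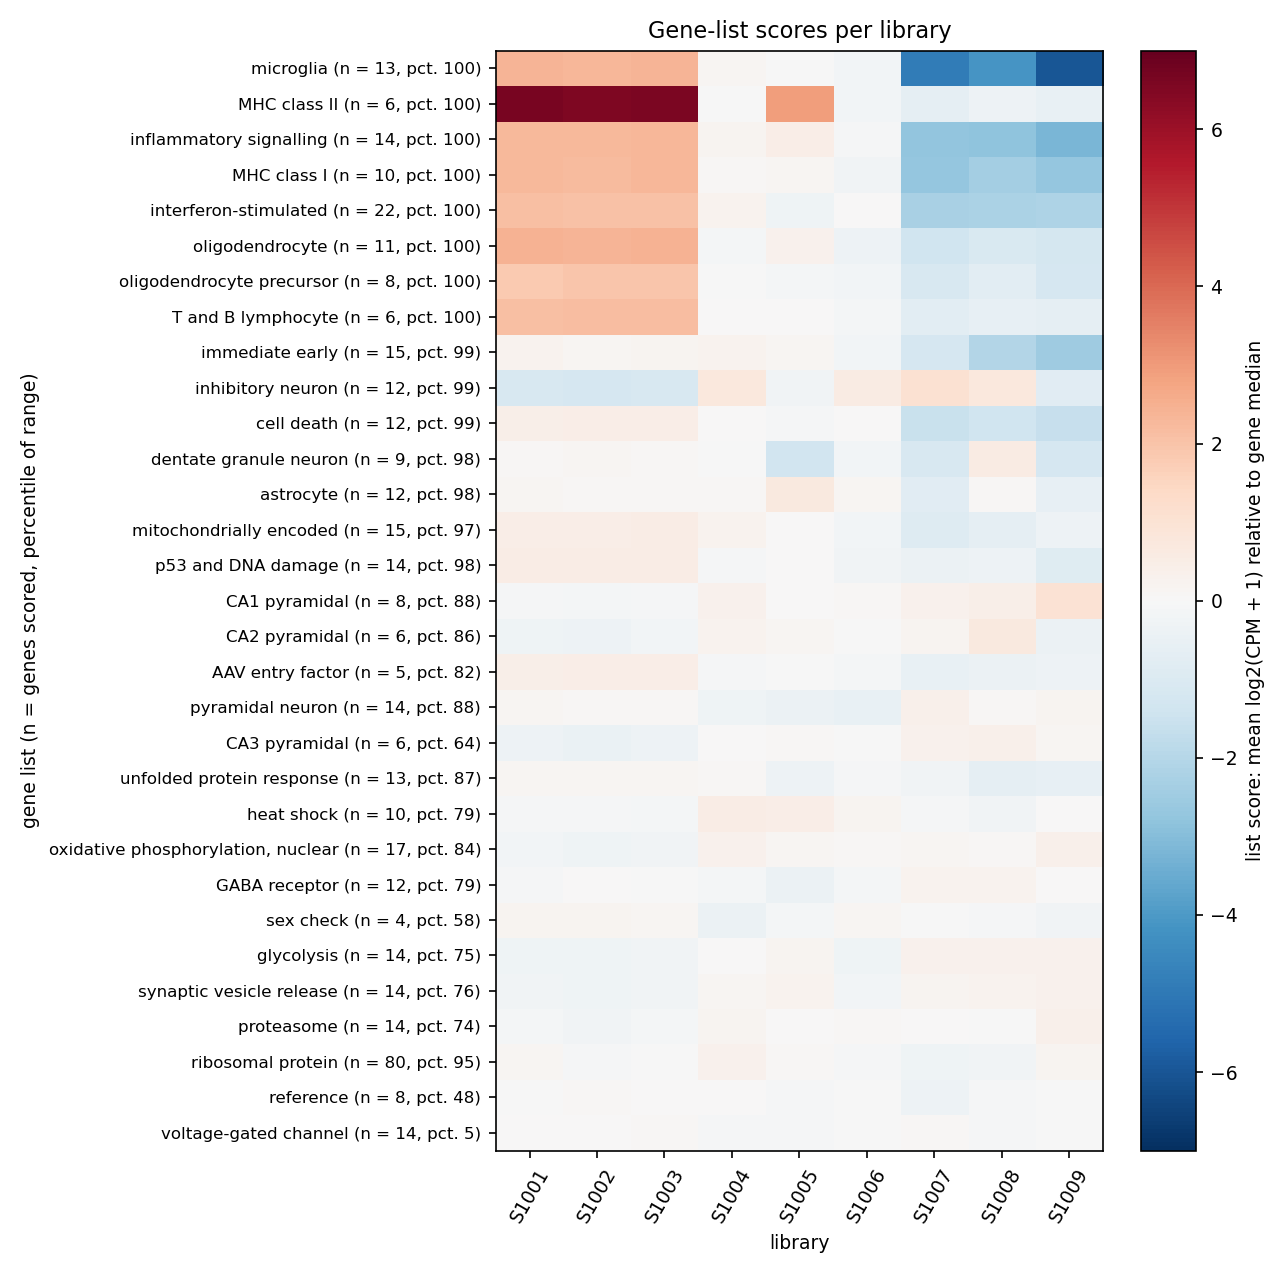
Score of each gene list in each library, as the mean log2(CPM + 1) of its members relative to each gene's median over the 9 libraries, with the number of genes scored and the percentile of the score range among matched random lists. The microglia list had the widest range, 8.37, and the voltage-gated channel list the narrowest, 0.18.

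Immediate early, cell death and p53 genes were uneven as well. Of the immediate early genes, 14 of 15 passed 2-fold, with a range of 2.76 (percentile 99.99). Fos, a transcription factor induced by activity and by tissue dissociation (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273), measured 949.9, 929, 947, 1430.2, 1555, 1103, 123, 37.8 and 15.4 CPM. Egr1 ranged from 315 to 1352 CPM and Btg2, an antiproliferative gene, from 10.8 to 619.6 CPM. Cell death genes ranged over 2.07 (percentile 99.87), with 7 of 12 past 2-fold. Casp8, an initiator caspase, ranged from 0.0616 to 26.7 CPM and Gsdmd, a pore-forming effector of pyroptosis, from 0.0616 to 24.8 CPM. Both are expressed by immune cells too, and their lowest levels rest on 1 count. The p53 and DNA damage list ranged over 1.35 (percentile 98.44, 93.54 without S1009), with 6 of 14 past 2-fold. Cdkn1a, a cell cycle inhibitor, measured 299, 250.2, 267, 42.2, 95.6, 31.5, 24.8, 18.5 and 15.8 CPM, and Bax, a mediator of apoptosis, ranged only from 88.1 to 111 CPM. The unfolded protein response and heat shock lists were at percentiles 87.34 and 79.8, and the former at 97.96 with the median of members as score. Markers of other cell types varied in the same libraries. In S1001 to S1009 the immediate early score was 0.22, 0.13, 0.18, 0.27, 0.12, -0.19, -1.15, -2.04 and -2.49, the cell death score 0.41, 0.46, 0.45, 0.03, -0.11, 0.00, -1.54, -1.42 and -1.61 and the p53 and DNA damage score 0.51, 0.51, 0.51, -0.06, 0.01, -0.26, -0.40, -0.33 and -0.83. The microglia score was 2.40, 2.31, 2.37, 0.12, -0.01, -0.18, -4.88, -4.13 and -5.97 and the oligodendrocyte score 2.42, 2.38, 2.43, -0.13, 0.32, -0.35, -1.37, -1.08 and -1.22. These values do not show which cells expressed the genes of these lists. Within the unfolded protein response and heat shock lists, Atf3 ranged from 0.555 to 344 CPM and Hspa1b, an inducible chaperone, from 3.57 to 101 CPM. Hspa1b is near-identical to its neighbour Hspa1a, at 17.0 to 115 CPM, so the division of counts between them is uncertain.

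Channel, synaptic and metabolic lists had few members past 2-fold. The voltage-gated channel list ranged over 0.18, at percentile 5.95, and 1 of its 14 members passed 2-fold. Scn2a, a sodium channel, ranged from 295 to 417 CPM. The synaptic vesicle release list was at percentile 76.41 and the GABA receptor list at 79.19, with 1 and 1 members past 2-fold. Snap25, a fusion protein of synaptic vesicles, ranged from 2834 to 4530.3 CPM, and Gabra2, a GABA receptor subunit, from 438 to 613 CPM. Nuclear oxidative phosphorylation, glycolysis and proteasome genes were at percentiles 84.44, 75.03 and 74.9, with 0, 2 and 0 members past 2-fold. Atp5b, a subunit of ATP synthase, ranged from 1425 to 2103 CPM and Pkm, a glycolytic enzyme, from 1183 to 2545 CPM. With the median of members as score, the synaptic vesicle release, GABA receptor, oxidative phosphorylation, glycolysis and proteasome lists reached percentiles 98.92, 99.62, 99.96, 99.06 and 97.07, all above 95.

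Ribosomal protein genes ranged over 0.56 (percentile 95.74), but reached percentile 90.15 without S1004, and 7 of 80 passed 2-fold. Rpl29 measured 8.85, 5.61, 8.08, 0.632, 47.9, 0.654, 0.942, 6.64 and 37.8 CPM, and Rpl4 ranged from 294 to 355 CPM. Ribosomal protein genes have many processed pseudogenes, so single values are uncertain. Mitochondrially encoded genes ranged over 1.44 (percentile 97.97, 93.43 without S1007). Of them mt-Cytb measured 3812, 3961, 4073, 2562, 2499, 2137, 1466, 1985 and 2756 CPM, and mt-Rnr1, a ribosomal RNA, ranged from 96.5 to 1119 CPM.

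Of the entry factors of adeno-associated virus, Tm9sf2, Gpr108 and Rpsa ranged from 217 to 383 CPM, 22.9 to 39.9 CPM and 89.3 to 141 CPM. AU040320, the mouse gene of the AAV receptor, ranged from 27.8 to 45.8 CPM. Pdgfra and Pdgfrb, growth factor receptors, ranged from 0 to 14.4 CPM and 0 to 0.914 CPM. Pdgfra is also in the oligodendrocyte precursor list, and it measured 10.2, 13.5, 14.4, 1.47, 3.17, 2.83, 0.0673, 0.305 and 0 CPM in S1001 to S1009. Which cells expressed Pdgfra is not shown by these values. The list was at percentile 82.52. Libraries were those of male animals by the labels, and Ddx3y, Eif2s3y, Kdm5d and Uty, on the Y chromosome, ranged from 52.1 to 93.5 CPM, 63.7 to 114 CPM, 9.84 to 21.4 CPM and 11.5 to 19.6 CPM. Xist, transcribed from the inactive X chromosome, ranged from 0 to 0.538 CPM, and the list was at percentile 58.09. The reference gene list was at percentile 48.31. Actb and Ywhaz ranged from 3202 to 4649 CPM and 1475 to 2289 CPM. Gapdh ranged from 0.945 to 5.61 CPM, a level that is uncertain because the gene has many near-identical pseudogenes among which the counting could divide or discard reads. Others among the 10 most abundant genes were Calm2, Malat1, Tmsb4x, Rtn1, Aldoa and Cpe, of which Calm2, a calmodulin, ranged from 6260.4 to 11592 CPM and Malat1, a nuclear noncoding RNA, from 3649.5 to 12302 CPM.

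Some genes departed in a single library. Wdfy1, an endosomal adaptor protein, measured 42.9, 42.9, 46.1, 39.8, 45.6, 45.2, 38.2, 53.8 and 4.87 CPM in S1001 to S1009, with the low value in S1009. Stat6, a transcription factor of interleukin signalling, measured 0.185 CPM in S1009 and at least 5.85 CPM elsewhere. Grem1, a secreted inhibitor of bone morphogenetic proteins, was lowest in S1005, at 1.38 CPM against a median of 18.8 CPM. BC002163 was listed at 11.4 CPM in S1005 and at a median of 101 CPM, but it is annotated as a processed pseudogene, so its values are uncertain.

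The 36 pairs of libraries were compared with a chi-square test against sampling noise, for which chi-square divided by its degrees of freedom would be near 1. The lowest values were 2.67 for S1001 and S1003, 2.82 for S1002 and S1003, and 5.14 for S1001 and S1002. The next was 24.3, for S1004 and S1005. No pair agreed within sampling noise, and all 9 libraries were kept. The test compares libraries, not conditions, and does not show that libraries come from separate RNA samples.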

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

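No paired analysis was possible because no library has a group. The number of genes at least 2-fold apart was 3911 and ranged from 3209 to 3659 when each library was left out in turn. It was 1955 with a pseudocount of 5 CPM, which shrinks low genes, and 7771 between the highest and lowest library, which is wider by construction. With a minimum mean of 10 CPM it was 1770 of 9646 genes, a smaller share than 3911 of 14787. Without S1002 and S1003 together, an alternative chosen after seeing the data, 2869 genes passed and 16 lists, the same ones as with all libraries, stood above percentile 95. The 16 lists became 26 when the score was the median of members, and the cause was not tested. They were 15 to 16 with each library left out and 13 with a minimum mean of 10 CPM. That minimum left the oligodendrocyte precursor and the T and B lymphocyte lists with fewer than 3 members, so they were not scored. Ribosomal protein genes dropped below percentile 95 with total counts alone (94.42), a pseudocount of 0.5 CPM (91.13) and without S1004 (90.15). Astrocyte genes did so without S1005 (86.91) and with a minimum of 10 CPM (94.53). The number of planned correlations that met the rule on gaps was 11, and 6 to 11 with each library left out (7 without S1004, 6 without S1008 and 7 without S1009), the cause not being tested. The biological coefficient of variation was 0.481 to 0.544 with each library left out. The first principal component held 81.5% of the variance of the 500 most variable genes and 65.5% over all genes with a mean of at least 1 CPM. Of the named genes' spreads under the alternatives, 2106 values stayed within 1.5 times the main value and 79 did not. Scaling alternatives moved the median gene of a library by at most 0.061 on the log2 scale. Levels below 0.1579 CPM in S1004 to 0.2459 CPM in S1001, depending on the library, rest on under 3 counts and cannot be ranked.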

Other observations

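The principal components and clustering were planned. Of the tests of explanations in this part, those of a single microglial source, of detected genes and of the closeness of libraries were chosen only after the result was seen, and the marker values of the plasma cell and border macrophage tests had not been looked at when their predictions were written. The genes named singly here were chosen after their values were seen. Cell types were tested only as sources of RNA other than the sorted neurons, and no biological explanation by dose or group was tested, because the labels give no group per library.

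Whole profiles fell into separate clusters. On the first principal component, which held 81.47% of the variance, S1001 to S1009 lay at -51.02, -50.59, -51.28, -17.01, -16.75, -13.15, 67.29, 59.58 and 72.94. On the second, with 16.96%, they lay at -21.85, -21.46, -21.79, 33.1, 27.22, 32.4, -9.67, -6.57 and -11.38. Average-linkage clustering on Spearman's rho across genes joined S1001, S1002 and S1003 at an average rho of 0.994, S1004, S1005 and S1006 at 0.975, and S1007, S1008 and S1009 at 0.972. The first 6 of these libraries joined at 0.932 and all 9 at 0.877. Genes are not independent replicates, and these clusters are not taken as doses.

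Other immune cell markers, from lists added after the data had been seen, differed in level. Neutrophil genes were near 0 in every library: S100a8, an abundant neutrophil calcium-binding protein, ranged from 0 to 0.0768 CPM and Ngp, a granule protein, from 0 to 0.246 CPM. Of dendritic cell genes, Itgax, an integrin shared with activated microglia, measured 55.5, 52.5, 52.8, 0.0526, 0.896, 0.0727, 0, 0.487 and 0 CPM in S1001 to S1009. Cd209a, a lectin, measured 2.38, 2.23, 2.90, 16.4, 16.4, 18.4, 0.404, 0 and 0.0616 CPM. Ccr7, a chemokine receptor, measured 3.61, 3.61, 4.12, 0.105, 0.0690, 0, 0, 0 and 0 CPM. Flt3, a cytokine receptor, was highest in S1008, at 7.55 CPM, and ranged from 2.38 to 7.55 CPM. Zbtb46 and Batf3, transcription factors, ranged from 0.670 to 6.03 CPM and 0.135 to 5.57 CPM, and Xcr1 and Clec9a, of cross-presenting dendritic cells, from 0 to 0.384 CPM and 0 to 0.183 CPM.

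Immune transcripts were abundant in some libraries of cells sorted as mCherry-fluorescent, a gate meant to select Cre-positive neurons. How well that gate kept immune cells out was not measured here. One microglial source of fixed composition is argued against, since 8 of 10 microglial genes varied more than 2-fold relative to C1qa, C1qb and C1qc over the 6 libraries with at least 1000 CPM of microglial genes, Tmem119 by 62.2-fold. Plasma cells may be a source in S1001, S1002 and S1003, where 9 of 10 plasma cell genes had their 3 highest values together with Igkc, against 1.27 expected at the share of all genes that do so; Mzb1 measured 27.9, 25.7, 27.7, 0, 0, 0, 0, 0.122 and 0 CPM and the exception, Tnfrsf17, was highest in S1004. Border macrophages may be a source in S1004, S1005 and S1006, where 10 of 10 of their genes had their 3 highest values together with Mrc1, against 0.472 expected; F13a1 measured 61.1, 70.0, 62.4, 348, 291, 286, 0.807, 6.21 and 0.308 CPM and Mrc1 89.0, 100.0, 102, 423, 346, 400.1, 0.471, 2.31 and 0.431 CPM. In each list 1 of the 10 genes was at 1 CPM or more in every library and 0 were in another list. The rule used ranks alone, so small differences counted as much as that of Mzb1. Fkbp11 counted at 1.80, 2.23 and 1.68 CPM in S1001 to S1003, against 1.58 CPM in S1008. Tnfrsf13b counted at 18.6, 19.3 and 19.7 CPM, against 12.7, 7.58 and 12.3 CPM in S1004 to S1006. The expected numbers were set after the tests had been run. Genes of other immune cells share these libraries too. The oligodendrocyte score was also highest in S1001, S1002 and S1003, at 2.42, 2.38 and 2.43. The tests therefore do not separate one immune cell type from another, or plasma cells from other non-neuronal sources. Whether immune cells were sorted, adhered to neurons or released RNA stays open.

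The number of detected genes ranged over 7572 between libraries. Library depth is argued against, since thinning every library to the smallest total left a range of 7710. A few genes taking most of the counts is argued against too, since without the 100 genes of highest mean over the libraries the range was 7651. Few starting molecules in some libraries may contribute and was not decided: genes with at least 20 counts in a library and 0 in its most similar library numbered 0, 0, 0, 13, 9, 5, 29, 87 and 62 in S1001 to S1009, and 1 library, S1008, had more of them than S1009, which had the fewest detected genes. A smaller variety of cells would also lower the number of genes and was not separated from it.

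S1001, S1002 and S1003 were closer to each other than other pairs, with 13 to 16 genes at least 2-fold apart per pair, against 583 or more in the other pairs. A single library deposited more than once is argued against, since the lowest chi-square over degrees of freedom of the 3 pairs was 2.67, above the 1 of sampling noise. A length-dependent step in preparing one RNA several times could produce such small differences and was not decided: the log2 ratio of the later-numbered to the earlier-numbered library correlated with exonic length across genes at a Spearman's rho of 0.257 for S1001 and S1002, 0.179 for S1001 and S1003 and -0.171 for S1002 and S1003, but also at 0.293 for S1004 and S1005 and -0.316 for S1002 and S1004, so the trend is not particular to these libraries. Whether these libraries come from separate animals, from pooled cells or from one RNA stays open, and the labels say only that replicates were biological.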
